A study of Homo sapiens with 11 samples.

How the data were processed

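RNA sequencing of 6 libraries was analysed, 3 labelled as a control knockdown and 3 labelled as an H2AS40 knockdown in MDA-MB-231 cells, with groups and replicate numbers taken from the sample titles. The labels' protocols name a miniprep kit for total RNA and an RNA library kit, without saying how messenger RNA was selected or whether strand was kept. The values deposited by the authors are gene-level TPM (transcripts per 1000000), in which a gene's reads are divided by its length and scaled to a common total. Each library summed to 1000000. The tool that estimated the TPM is not given in the sources used here. The genome build hg38 and the tools Bowtie2 and MACS2 are named, with no version and no role, per the submitters' processing notes. Because TPM keep no depth, total reads per library are unknown, and a value of 0 may be a failed estimate. Replication histone messages mostly lack a poly(A) tail and have near-identical copies, so selection and read sharing can change their values. The 5 chromatin immunoprecipitation samples were not analysed here.

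The table listed 37247 gene identifiers. Unversioned Ensembl identifiers were matched to symbols for 34436, and 2811 kept their identifier, including 952 of the tested genes (6.7%). List genes with no match were H2AC18, H2AC19, H3C2, H3C3, H3C15, TNF, SOD2 and RPS18, and these were not tested. Coordinates are from a RefSeq gene table of the GRCh38.p14 assembly, matched by symbol, and were not taken from the deposited values.

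Genes with at least 1 TPM in at least 3 of the 6 libraries were kept, which left 14160. Values were analysed as log2(TPM + 1), so fold changes are on that scale and understate those of low genes. The comparison used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Gene lists, 28 in all, were tested with limma's camera at a preset correlation of 0.01 where at least 3 members were tested, which gave 26 tests with their own Benjamini-Hochberg adjustment. The same lists were tested with an estimated correlation and with fry. Summed TPM of H2A genes, and of the other replication histones, were compared by a two-sided exact permutation test. The S40-type genes were set as H2AC7 and H2AC25 from recollected protein sequences, since no sequence was at hand to check them. Design, gene lists, named-gene rule and processing alternatives were set before the data were examined. Exceptions are named as chosen after the data were seen.

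Named genes were canonical H2A genes with a mean of at least 1 TPM in either group, OGT and OGA, and the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 5 TPM and no overlap between groups. Up to 3 called members of each list with the largest change were added, or the member with the smallest p where none was called. Other genes were named from counts after their values were seen. Some genes that the rule names are not reported here. No library duplicated another: at most 0.113% of tested genes had identical TPM in any pair.

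Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, or 5 TPM), median-of-ratios and quantile scaling, rescaling without mitochondrially encoded genes, eBayes without a trend, the replicate number as a term, and leaving out each library. Removal of a trend on gene span, the genes with a known span alone and a wider S40-type sum were added after the data were seen. The limma step was tested on simulated data for this comparison, with 14160 genes, the observed means and spreads, and 200 changed genes in each of 5 sets. It recovered 12.8% of genes changed by 0.25 on the log2 scale, 57.0% of those changed by 0.5 and 85.5% of those changed by 1, and 4.89% of called genes were false. The changed genes were drawn from those at about 5 TPM or more on average, and noise was independent between genes. These shares therefore do not cover lower genes and do not allow for correlation between genes.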

Results

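Gene expression was measured by RNA sequencing in MDA-MB-231, an established human cell line derived from a triple-negative breast cancer. The labels name 3 libraries as a control knockdown (Control-KD) and 3 as a knockdown of H2AS40. H2AS40 stands for forms of histone H2A with a serine at residue 40, which in the modified form named in the series carries a single sugar, O-linked N-acetylglucosamine. The question set by the series title was how gene expression differs in cells with that knockdown. The series holds 11 samples in all, and the 5 chromatin immunoprecipitation samples (the modified H2A, 3 histone H3 methylation marks and input) were not analysed here. Values were in transcripts per 1000000 (TPM) and summed to 1000000 in each library, so the sequencing depth was unknown and no counting interval could be given. Between 14073 and 14120 genes reached 1 TPM in a library. Correlations of log2(TPM + 1) across tested genes, which are not independent replicates, ran from 0.982 to 0.989 within groups and from 0.982 to 0.987 between groups. Control-KD replicate 3 stood apart, at -31.2 on a first principal component that held 29.6% of the variance, where the other libraries lay between -0.784 and 12. The labels did not say whether replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

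No fall of the S40-type H2A genes was detected in the libraries labelled H2AS40-KD. H2AC25 (ENSG00000181218.5), a histone H2A gene on chromosome 1 of GRCh38 from 228457364 to 228457873, had 32.4, 33.5 and 31.3 TPM in Control-KD and 33.3, 34.8 and 32.6 TPM in the libraries labelled H2AS40-KD. The means were 32.4 ± 1.10 TPM and 33.6 ± 1.14 TPM (SD, n = 3 each, two-sided exact permutation p = 0.40). H2AC7 was listed at 0.00, 0.00 and 2.97 TPM in Control-KD and at 0.968, 0.00 and 0.256 TPM in the libraries labelled H2AS40-KD, below the filter for testing. Their sum was 33.4 ± 0.911 TPM against 34.0 ± 1.03 TPM (SD, n = 3 each), with a two-sided exact permutation p of 0.50, where 3 libraries against 3 cannot give less than 0.10. As a share of the TPM of all canonical H2A genes the same pair had the other sign, with 15.4 ± 0.341% against 14.9 ± 0.603% (SD, n = 3 each, exact permutation p = 0.30), beside a sum over all canonical H2A genes of 217 ± 9.47 and 229 ± 4.61 TPM (SD, n = 3 each, exact permutation p = 0.10). The 95% interval of limma's fold change for H2AC25 excluded a fall of more than 5.4%. That bound is for 1 way of processing, and the fold change had the other sign with the gene-span trend removed. The labels name the S40 type but no gene, and this pair was taken from recollection of the protein sequences, which could not be checked against a sequence and may be incomplete. With H2AC4 and H2AC8 counted as S40-type as well, an alternative chosen after the data were seen, the sum was 58.1 ± 3.28 TPM against 63.6 ± 2.0 TPM (SD, n = 3 each, exact permutation p = 0.10). Because these values do not show the knockdown that the labels name, the libraries are called by their label throughout, and each direction given is between labels.

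Among the other canonical H2A genes, 12 were tested and 0 were called by limma, both over all genes and adjusted over the list alone, with 3 at an unadjusted p under 0.05. H2AC6, the most abundant, had 82.0 ± 1.19 TPM (SD, n = 3) in Control-KD and 90.8 ± 0.922 TPM (SD, n = 3) in the libraries labelled H2AS40-KD (limma adjusted p = 0.122). H2AC8 had 23.8 and 29.1 TPM (limma adjusted p = 0.233), and H2AC20 had 28.5 and 22.6 TPM (limma adjusted p = 0.27). The 12 genes had a median log2 fold change of 0.12 and a mean of -0.06, and camera placed them upward with an adjusted p of 0.762. Without Control-KD replicate 1 the test was downward (camera adjusted p = 0.887). Genes of this family are nearly identical in sequence, so reads may have been divided between copies, and their values are uncertain. OGT, which adds O-linked N-acetylglucosamine, had 34.1 and 33.1 TPM (limma adjusted p = 0.834), and OGA, which removes it, had 71.5 and 77.1 TPM (limma adjusted p = 0.408). Of 34 tested genes for the other replication histones, H2BC5 rose from 187 ± 4.02 to 218 ± 5.07 TPM (SD, n = 3 each, limma adjusted p = 0.0353). It was also the 1 call adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0856) except without replicate 3 labelled H2AS40-KD (camera adjusted p = 0.0166). The summed TPM of the matched genes in that list was 1587 ± 17.6 in Control-KD and 1693 ± 26.2 in the libraries labelled H2AS40-KD (SD, n = 3 each, exact permutation p = 0.10).

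**Figure D1:**
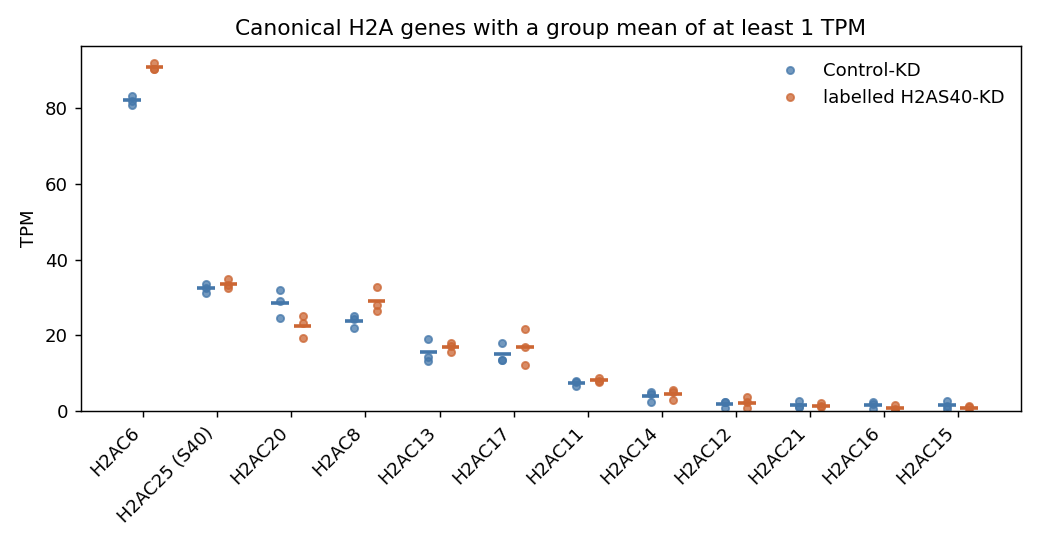
TPM (vertical axis) of each canonical H2A gene with a group mean of at least 1 TPM, with 1 point per library and a line at each group mean, for Control-KD and the libraries labelled H2AS40-KD. H2AC25 lay between 31.3 and 33.5 TPM in Control-KD and between 32.6 and 34.8 TPM in the libraries labelled H2AS40-KD.

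The libraries labelled H2AS40-KD differed from Control-KD in 178 of 14160 tested genes, by small amounts. IL24, a cytokine of the interleukin-10 family, had the largest rise among the genes named by rule, from 15.6 ± 0.636 to 30.6 ± 1.47 TPM (SD, n = 3 each), a log2 fold change of 0.93 with a limma adjusted p of 0.00444. PLAT, the tissue plasminogen activator, had the largest fall on the log2(TPM + 1) scale among those named by rule. It went from 32.8 ± 1.25 to 18.1 ± 3.08 TPM (SD, n = 3 each), a log2 fold change of -0.83 with a limma adjusted p of 0.0293. In mean TPM, PDE1C and TSPAN8 changed by more (-49.1% and -47.1%, against -44.7% for PLAT). By limma, 73 genes were higher and 105 were lower, with a median absolute log2 fold change of 0.35, and 133 of the 178 changed by less than 0.5 on the log2(TPM + 1) scale. The groups did not overlap in 24.2% of all tested genes, where chance gives 10%. The called genes with at least a 2-fold change on the log2(TPM + 1) scale had group means of at most 7.02 TPM. They are named here after their values were seen. GRIK4, a glutamate receptor subunit (7.02 ± 3.79 to 0.751 ± 0.466 TPM), and GLI2, a transcription factor of hedgehog signalling (3.40 ± 0.528 to 1.07 ± 0.172 TPM), fell (SD, n = 3 each), as did ENSG00000258680, from 1.17 TPM to a listed value of 0. CIDECP2 (0.849 to 4.52 TPM) and ENSG00000278780.4 (0.403 to 3.90 TPM) rose.

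Among called genes with a symbol, a mean of at least 5 TPM and no overlap between groups, the largest rises after IL24 were SCG5, a chaperone of the secretory pathway (7.64 to 14.7 TPM), CSF2, a myeloid growth factor (19.9 to 33.9 TPM), AKR1C2, an aldo-keto reductase (49.5 to 80.1 TPM), and CXCL8, a neutrophil-attracting chemokine (18.8 to 30.5 TPM). CYP1A1, a target of the aryl hydrocarbon receptor, rose from 85.7 ± 1.84 to 129 ± 1.93 TPM (SD, n = 3 each), with a limma adjusted p of 0.00363. The transcription factors KLF10 (94.4 to 141 TPM), MYC (207 to 299 TPM) and NR1D1 (64.3 to 92.5 TPM) and the amino acid transporter SLC43A1 (10.8 to 16 TPM) also rose. Under the same rule, the largest falls after PLAT were PDE1C, a cyclic nucleotide phosphodiesterase (6.94 to 3.54 TPM), TSPAN8, a tetraspanin (9.49 to 5.02 TPM), SEMA3A, a secreted guidance cue (17.6 to 9.78 TPM), and RSAD2, the antiviral protein viperin (14.6 to 8.31 TPM). SLCO4A1, an organic anion transporter, fell from 37.9 to 22.5 TPM, and FN1, fibronectin, fell from 31.1 ± 2.30 to 18.3 ± 1.71 TPM (SD, n = 3 each). TIMP3, an inhibitor of matrix metalloproteinases (55.4 to 34.4 TPM), EDIL3, an integrin ligand (10.6 to 6.36 TPM), and BMP4, a secreted growth factor (52.9 to 33.3 TPM), fell as well. These 20 genes had limma adjusted p-values from 0.00363 to 0.0496.

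Most single-gene calls were lost when 1 library was left out, except for Control-KD replicate 3. Fewer libraries also give less power, so the losses alone do not show that particular libraries set the calls. Fits of equal size still differed, so the number of calls kept depended on which library was left out. Of the 178 genes, 6 were still called without Control-KD replicate 1, 8 without Control-KD replicate 2 and 117 without Control-KD replicate 3. Without replicates 1, 2 and 3 labelled H2AS40-KD, 7, 5 and 33 were still called. The sign was kept in 177 of 177 genes tested in each of these fits. The groups did not overlap in any of the 178 genes, so leaving out 1 library could not have reversed a sign. CST1, KLF10, IFIT1, CYP1A1 and PPP1R15A passed in all 6 of those fits, and were singled out after their values were seen. Without an intensity trend 9 were still called. A trend of fold change on the span of the gene could be removed for the 13100 tested genes with a known span, an alternative chosen after the data were seen. Among these genes 82 were higher and 123 lower with the trend kept, and 53 were higher and 128 lower with it removed, a share of 29.3% higher, where 41.0% were higher among the calls over all tested genes.

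Interferon-response genes were lower as a group in the libraries labelled H2AS40-KD. IFIT1, an interferon-induced protein that binds foreign RNA, encoded on chromosome 10 from 89392623 to 89406487, fell by 36.3%, from 166 ± 4.57 to 106 ± 2.38 TPM (SD, n = 3 each), with a limma adjusted p of 0.00332. IFI44 fell from 76.8 ± 3.46 to 53.2 ± 2.29 TPM (SD, n = 3 each), and RSAD2 fell by 43.0%. Of 33 tested members, 13 fell and 0 rose by limma over all genes; adjusted over the list alone, 28 fell and 2 rose. Those that fell included IFIT2, IFIT3, IFITM1, ISG15, MX1, OAS1, OAS2, OAS3 and the RNA sensor RIGI. The 2 that rose over the list alone were IRF1 (53.8 to 63.8 TPM) and IRF7 (2.39 to 4.32 TPM), both transcription factors of the pathway. Of the 33, 31 had a negative log2 fold change, and the median was -0.32 (camera adjusted p = 6.7e-25). This was the list whose call held with an estimated correlation (adjusted p = 0.0122), among 9 of 26 tested lists past the threshold with the preset correlation. The medians per library were -0.31, -0.30 and -0.36 in the libraries labelled H2AS40-KD relative to the Control-KD mean. In the same direction, a list of blood cell markers had a median of -0.44 over 5 tested genes, 3 of them negative (camera adjusted p = 0.0299, and adjusted p = 0.27 with an estimated correlation). Their median was -0.22, -0.24 and -0.19 without Control-KD replicate 1, 2 or 3, where the tested members may differ. Mitochondrially encoded genes had a median of -0.05 (camera adjusted p = 0.0197, and adjusted p = 0.587 with an estimated correlation), with -0.08, -0.08 and 0.03 in the libraries labelled H2AS40-KD.

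Inflammatory genes that NF-kappaB regulates were higher in the libraries labelled H2AS40-KD. CXCL8 rose from 18.8 ± 0.671 to 30.5 ± 0.977 TPM (SD, n = 3 each), CSF2 from 19.9 ± 3.19 to 33.9 ± 0.623 TPM (SD, n = 3 each), and TNFAIP3, an inhibitor of the same pathway, from 27.7 ± 2.61 to 38.1 ± 1.19 TPM (SD, n = 3 each). NFKBIA, another inhibitor of the pathway, was the remaining call, from 90.5 to 115 TPM (limma adjusted p = 0.0182). Of 19 tested members, 4 rose and 0 fell by limma over all genes; adjusted over the list alone, 11 rose. The median log2 fold change was 0.34, with 18 positive (camera adjusted p = 1.5e-08), but the call did not hold with an estimated correlation (adjusted p = 0.0711). TNF and SOD2 had no matched identifier and were not tested.

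MYC and genes of ribosome assembly in the nucleolus were slightly higher in the libraries labelled H2AS40-KD. MYC, a growth-promoting transcription factor on chromosome 8 from 127735434 to 127742951, rose from 207 ± 11.5 to 299 ± 17.7 TPM (SD, n = 3 each). It was the 1 call over all genes among 24 tested members; adjusted over the list alone 2 rose, the other being NOP2, a methyltransferase of ribosomal RNA (143 to 164 TPM). The median log2 fold change was 0.12, with 20 positive (camera adjusted p = 1.8e-05, and adjusted p = 0.0585 with an estimated correlation). Of 43 ribosomal protein genes 0 were called by limma, with 6 at an unadjusted p under 0.05 and 0 adjusted over the list alone. RPS9 had the smallest p (124 and 141 TPM), and the list median was -0.02 (camera adjusted p = 0.0856, and adjusted p = 0.617 with an estimated correlation). The test was upward under quantile normalization (camera adjusted p = 0.145). This list passed without Control-KD replicate 1 (camera adjusted p = 0.0123) and without replicate 3 labelled H2AS40-KD (camera adjusted p = 0.0166). It also passed under median-of-ratios scaling (camera adjusted p = 0.0341) and with the gene-span trend removed, at a median of -0.07 (camera adjusted p = 6.0e-11). Each of these passes was at the preset correlation.

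Genes of the mesenchymal state and its matrix were divided, with more falls than rises in the libraries labelled H2AS40-KD. FN1 fell by 41.1%, and S100A4, a calcium-binding protein linked to cell motility, fell from 215 ± 8.07 to 139 ± 11.5 TPM (SD, n = 3 each). CDH11, a mesenchymal cadherin, fell from 38.0 ± 1.77 to 27.3 ± 1.39 TPM (SD, n = 3 each). Of 24 tested members, 5 fell and 0 rose over all genes, the others being the membrane-bound metalloproteinase MMP14 and the matricellular protein CCN2; adjusted over the list alone, 11 fell and 3 rose. Those that rose included the transcription factors SNAI1 (7.36 to 11.7 TPM) and SNAI2 (24.9 to 30.9 TPM). The median log2 fold change was -0.16 (camera adjusted p = 0.00664, and adjusted p = 0.0964 with an estimated correlation). With no filter on low values the call ended at a median of -0.05 (camera adjusted p = 0.0937), while the median was -0.25 without Control-KD replicate 1 and -0.26 without replicate 1 labelled H2AS40-KD. VIM, the intermediate filament vimentin, had 2258 and 2270 TPM. The median of the blood cell markers was also negative (-0.44, but -0.19 to -0.24 without 1 Control-KD library, where the tested members may differ). So was that of the mitochondrially encoded genes (-0.05, but 0.03 in replicate 3 labelled H2AS40-KD). Of 25 epithelial genes, LAMB3, a laminin chain, fell from 125 to 106 TPM, also the 1 call adjusted over the list alone, and the list did not pass (camera adjusted p = 0.323).

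Glycolysis, hypoxia-responsive and mitotic genes were lower by small amounts in the libraries labelled H2AS40-KD. SLC2A1, the glucose transporter GLUT1, fell from 220 ± 5.07 to 176 ± 8.73 TPM (SD, n = 3 each), PGK1 from 412 ± 11.9 to 351 ± 14 TPM (SD, n = 3 each), and LDHA, lactate dehydrogenase A, from 1217 ± 22.4 to 1049 ± 17.7 TPM (SD, n = 3 each). These were the 3 calls among 22 glycolysis genes, with 8 falls adjusted over the list alone and a median of -0.07 (camera adjusted p = 1.2e-05, and adjusted p = 0.0585 with an estimated correlation). Of 19 hypoxia-responsive genes, P4HA1, a collagen prolyl hydroxylase (26.2 to 18.8 TPM), and NDRG1 (142 to 105 TPM) fell; adjusted over the list alone, 7 fell and BHLHE40 rose. Their median was -0.13 (camera adjusted p = 2.3e-04, and adjusted p = 0.0961 with an estimated correlation), or -0.08 without replicate 3 labelled H2AS40-KD, and VEGFA, the vascular growth factor, had 95 and 94.8 TPM. Of 31 mitotic genes, TOP2A, topoisomerase II alpha, fell from 109 ± 2.60 to 92.9 ± 1.92 TPM (SD, n = 3 each). Adjusted over the list alone 8 mitotic genes fell, CCNB1 and PLK1 among them, and the median was -0.10 (camera adjusted p = 8.0e-07, and adjusted p = 0.0961 with an estimated correlation). Of 37 DNA replication genes 0 were called by limma, with 7 at an unadjusted p under 0.05, and MCM7, a helicase subunit, had 271 and 304 TPM (limma adjusted p = 0.0551). The median of the blood cell markers had the same direction as these lists (-0.44, but -0.19 to -0.24 without 1 Control-KD library, where the tested members may differ). So did that of the mitochondrially encoded genes (-0.05), except for 0.03 in replicate 3 labelled H2AS40-KD.

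**Figure D2:**
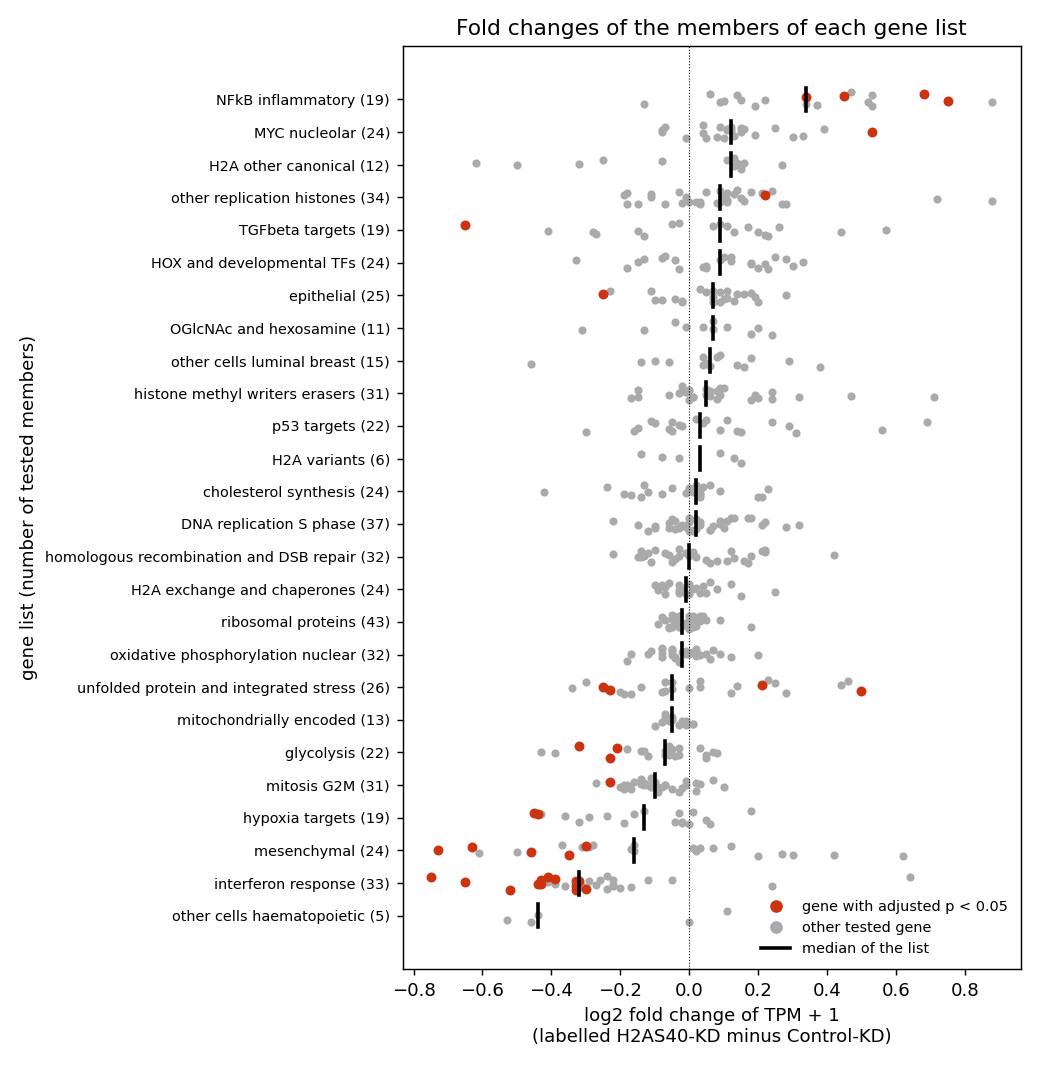
Log2 fold change of TPM + 1 (horizontal axis, libraries labelled H2AS40-KD minus Control-KD) of each tested member of 26 gene lists, with called genes in red and a bar at each list's median. The interferon list had a median of -0.32 with 13 falls, and the NF-kappaB list a median of 0.34 with 4 rises.

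Genes of the unfolded protein and integrated stress responses went both ways in the libraries labelled H2AS40-KD. PPP1R15A, a phosphatase subunit that restores translation, rose from 342 ± 2.27 to 484 ± 9.38 TPM (SD, n = 3 each), with a limma adjusted p of 0.00332, and the transcription factor ATF4 rose from 338 to 390 TPM. The chaperones CALR (655 to 559 TPM) and HSP90B1 (237 to 199 TPM) fell. Adjusted over the list alone, 6 of 26 rose and 8 fell. The median was -0.05, the mean 0.01 and the test downward (camera adjusted p = 0.44). BMP4 was the 1 call, a fall, among 19 genes of the TGF-beta list, with 4 rises and 3 falls adjusted over the list alone (camera adjusted p = 0.416).

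The remaining lists had 0 calls by limma over all genes, where 2337 of all tested genes had an unadjusted p under 0.05. Members at an unadjusted p under 0.05 numbered 2 of 11 for O-linked N-acetylglucosamine and hexosamine genes, 6 of 32 for nuclear genes of oxidative phosphorylation, 5 of 22 for p53 targets, 6 of 32 for homologous recombination and 7 of 24 for cholesterol synthesis. They numbered 4 of 31 for histone methylation enzymes, 1 of 24 for H2A exchange factors and chaperones, 4 of 24 for HOX and developmental factors and 1 of 6 for H2A variants. Camera adjusted p-values were 0.416 for O-linked N-acetylglucosamine and hexosamine genes, 0.169 for nuclear genes of oxidative phosphorylation, 0.187 for DNA replication, 0.689 for p53 targets, 0.904 for homologous recombination and 0.44 for cholesterol synthesis. They were 0.169 for histone methylation enzymes, 0.895 for H2A exchange factors and chaperones, 0.202 for HOX and developmental factors and 0.904 for H2A variants. Median, mean and test differed in sign for H2A variants (median 0.03, test downward), cholesterol synthesis (median 0.02, mean -0.02, test downward), H2A exchange factors (median -0.01, mean 0.01, test downward) and homologous recombination (median -0.00, mean 0.02, test downward). Fry placed H2A variants, H2A exchange factors and homologous recombination upward. Camera also placed H2A variants upward without Control-KD replicate 2, and homologous recombination upward without Control-KD replicate 3. Examples with the smallest p in their lists were KDM6B, a histone H3 demethylase (15.1 and 25.6 TPM, limma adjusted p = 0.122), and XPC, a DNA damage sensor (28.0 and 22.5 TPM, limma adjusted p = 0.077). They also included CHAF1A, a chromatin assembly factor (52.2 and 62.3 TPM, limma adjusted p = 0.0666), and H2AZ2, a histone variant (280 and 253 TPM, limma adjusted p = 0.122). Values in Control-KD and the libraries labelled H2AS40-KD were 64.6 and 73.2 TPM for GNPDA1, of hexosamine turnover, 267 and 238 TPM for NDUFB8, of respiratory complex I, and 12 and 14.1 TPM for HOXB9. The histone methylation list passed without Control-KD replicate 1 (camera adjusted p = 0.0232). Adjusted over the list alone, MCM7, CHAF1A, GADD45A and INSIG1 were among the genes that rose, and XPC and H2AZ2 among those that fell. Adjusted over the list alone, 1 gene of cholesterol synthesis rose and 1 fell, and 0 passed among the genes of hexosamine and O-linked N-acetylglucosamine, oxidative phosphorylation, homologous recombination, histone methylation, and HOX and developmental factors.

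Markers of other cells and of RNA quality were measured beside these groups. Of 14 blood cell markers, 5 were tested, 3 had an unadjusted p under 0.05 and 0 were called by limma: CD68 (60.5 and 44.4 TPM), LAPTM5 (7.14 and 4.65 TPM), CD14 (1.33 and 0.696 TPM), CORO1A (12.5 and 12.5 TPM) and HBA1 (6.57 and 7.22 TPM) in Control-KD and the libraries labelled H2AS40-KD. The list passed with a median of -0.44 (camera adjusted p = 0.0299, and adjusted p = 0.27 with an estimated correlation), and CD68 and LAPTM5 fell when adjusted over the list alone. The call ended without Control-KD replicate 1, 2 or 3 (camera adjusted p = 0.0687, 0.0834 and 0.28), where the median was -0.22, -0.24 and -0.19, and without replicate 1 labelled H2AS40-KD (0.0708). Each such fit applied the filter of 1 TPM in 3 libraries to the libraries left, and CD14 lay near it. The tested members may therefore differ, so these medians need not depend on any 1 library. The call also ended with a filter of 5 TPM, at a median of -0.22 (camera adjusted p = 0.0984), and with no filter, at a median of 0.00 (camera adjusted p = 0.383). The 15 luminal breast markers did not pass (camera adjusted p = 0.187), with 5 at an unadjusted p under 0.05, 0 called by limma, and AGR2 and XBP1 (193 and 212 TPM) rising when adjusted over the list alone. Of the stromal and endothelial markers 2 were tested, and COL1A1 had 6.48 and 7.16 TPM (limma adjusted p = 0.809). Mitochondrially encoded genes held 3.19% to 3.47% of the TPM of a library, and their 13 members had a median of -0.05 with 0 called by limma, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.0197, and adjusted p = 0.587 with an estimated correlation). MT-ND3 had 3357 and 3202 TPM. The medians per library were -0.08, -0.08 and 0.03 in the libraries labelled H2AS40-KD relative to the Control-KD mean. The list call ended without Control-KD replicate 3 (camera adjusted p = 0.154), without replicate 1 or 2 labelled H2AS40-KD (0.273 and 0.145, at a median of -0.03 each), under quantile normalization (0.588, at a median of -0.01) and without a trend (0.15). Without replicate 3 labelled H2AS40-KD the median was -0.08 (camera adjusted p = 6.6e-07).

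**Figure D3:**
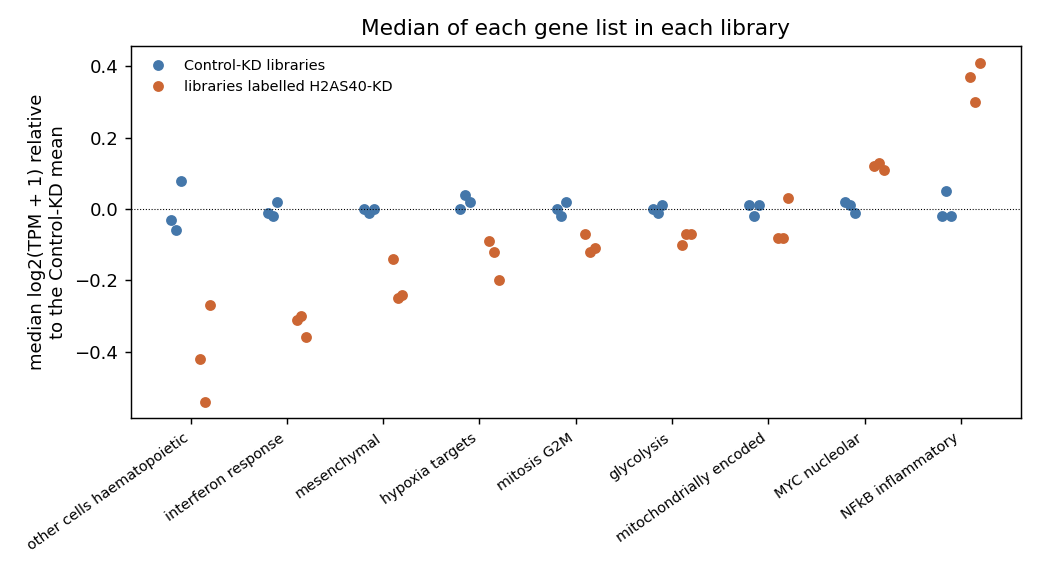
Median log2(TPM + 1) of each called gene list in each library, relative to the Control-KD mean (vertical axis), with 1 point per library. The interferon medians were -0.31, -0.30 and -0.36 in the libraries labelled H2AS40-KD and -0.01, -0.02 and 0.02 in Control-KD.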

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

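The gene-span trend, the test of genes with a known span alone and the wider S40-type sum (5.51 TPM higher, in the same direction) were chosen after the data were seen. Pseudocounts of 0.1 and 0.5, both scalings and rescaling without mitochondrial genes kept the counts of higher and lower genes within 1.5 times of 73 and 105. Called genes kept their sign in every setting where they were tested. The groups did not overlap in any of the 178 called genes. That fixed this outcome in advance, except under the scalings, the rescaling and the removal of the gene-span trend. With no filter, 43 genes were higher, 55 lower and 1 at least 2-fold higher, with 23967 genes tested. With a filter of 5 TPM, the genes called at 2-fold in the report (CIDECP2, ENSG00000278780.4, GRIK4, GLI2 and ENSG00000258680) were not tested, 0 were at least 2-fold lower, and 1 was at least 2-fold higher, RPL38P4 (4.16 and 12.2 TPM, limma adjusted p = 0.0465, against 0.0602 with all tested genes). Without a trend, 5 were higher, 5 lower, 0 at least 2-fold higher and 1 at least 2-fold lower, and the cause was not tested. CIDECP2 and ENSG00000278780.4 have no known span. Among the genes with one, 1 was at least 2-fold higher with the trend kept (RPL38P4) and 0 with it removed, and 2 were at least 2-fold lower in both. With fewer samples, leaving out 1 library gave 3 to 74 higher genes, 2 to 85 lower genes, 0 to 5 at least 2-fold higher and 0 to 5 at least 2-fold lower. With an estimated correlation 1 list passed, and with fry 8 did.

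The replicate number as a block gave 0 higher and 0 lower genes (2032 at an unadjusted p under 0.05), 0 at least 2-fold in either direction, and the same 9 lists, so it changed no list call. Same-numbered libraries did not deviate together (r = -0.01, -0.06 and -0.00), so these values gave no sign of a pairing by number. The labels do not say whether the libraries were paired, and these correlations cannot settle it.

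The S40-type difference had the other sign as a share of canonical H2A TPM (-0.518 percentage points), since the mean of the whole sum went from 217 to 229 TPM and that of the S40-type sum from 33.4 to 34.0 TPM. H2AC25 had the other sign with the gene-span trend removed (-0.01), and the cause was not tested. Leaving out 1 library gave log2 fold changes of -0.27 to 0.17 for H2AC21, -0.18 to 0.53 for H2AC12, -0.05 to 0.35 for H2AC17, -0.10 to 0.39 for H2AC14, -0.07 to 0.03 for OGT and -0.04 to 0.28 for COL1A1. Ribosomal protein genes passed under median-of-ratios scaling (0.0341) and, with the gene-span trend removed, so did they (6.0e-11), oxidative phosphorylation (0.00101) and histone methylation enzymes (0.0162), all as camera adjusted p. Sequencing depth is unknown, so what it limits could not be given.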

Other observations

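The gene lists on oxidative stress, protein translocation, integrins and immediate-early genes, the test on gene span for the NF-kappaB list and the question of knockdown reagents were chosen after the called genes had been seen, as was the wider S40-type sum.

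Of 35 tested genes of protein entry into the endoplasmic reticulum and N-glycosylation, 5 fell and 0 rose in the libraries labelled H2AS40-KD, and 33 had a negative log2 fold change (median -0.13). STT3A and DDOST, subunits of the oligosaccharyltransferase, fell from 118 ± 5.03 to 98.4 ± 2.31 TPM and from 170 ± 4.42 to 144 ± 1.88 TPM (SD, n = 3 each), and the translocon protein SSR1 fell from 172 to 142 TPM. Of 29 tested integrin and adhesion genes, 4 fell and 0 rose (median -0.15), with ITGB1 going from 371 ± 2.65 to 308 ± 8.08 TPM (SD, n = 3 each), ITGA6 from 64.6 to 46.2 TPM and ITGA2 from 33.3 to 26.2 TPM. The median of the blood cell markers had the same direction as both groups (-0.44, but -0.19 to -0.24 without 1 Control-KD library, where the tested members may differ). So did that of the mitochondrially encoded genes (-0.05, but 0.03 in replicate 3 labelled H2AS40-KD). Of 26 tested targets of the antioxidant regulator NRF2, 5 rose and 0 fell (median 0.07), among them NQO1 from 478 ± 3.12 to 564 ± 4.86 TPM (SD, n = 3 each), SQSTM1 from 1482 to 1802 TPM and FTH1 from 5081 to 5824 TPM. These genes were named after their values were seen.

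Each group was a hypothesis from its called genes, so the test used the members that had not been called. Of 30 such translocon and N-glycosylation genes, 28 were negative with a median log2 fold change of -0.11 (camera p = 1.0e-09, and p = 0.0128 with an estimated correlation, which is 0.0257 adjusted over the 4 added lists). Of 25 such integrin and adhesion genes, 22 were negative with a median of -0.10 (camera p = 9.0e-06, and p = 0.00779 with an estimated correlation, 0.0257 adjusted). Of 21 such targets of the transcription factor NRF2, 15 were positive with a median of 0.04 (camera p = 0.0352), and the p was 0.0823 with an estimated correlation, 0.11 adjusted. A coordinated fall may therefore reach beyond the called genes for the first 2 groups, while the NRF2 group depends on the preset correlation. The adjustment over 4 lists was milder than that over the 26 fixed lists. There, a camera p of 0.00634 for glycolysis with an estimated correlation became 0.0585. The first 2 groups are therefore not shown to be firmer than fixed lists whose calls did not hold. Fixed lists already held 3 of the 30, 1 of the 25 and 1 of the 21 genes. These tests used the libraries in which the groups were noticed.

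Interferon-response genes were lower in the libraries labelled H2AS40-KD, with a median of -0.32 over 33 genes. Leaving out any 1 library left the median at -0.29 or further from 0, and median-of-ratios or quantile scaling left it at -0.32 or further, which argues against 1 library or the scaling as the whole cause. Shorter genes tended to be higher (Spearman rho -0.17 across 13100 genes, which are not independent replicates), and removing that trend left a median of -0.35, which argues against gene span. A difference in the interferon response that the control and targeting reagents provoke may produce the same pattern. With 0 other knockdown groups in the design, this cannot be told apart from an effect of the target, and the S40-type levels, in which no fall was detected, leave both open.

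No fall of the S40-type H2A genes was detected in the libraries labelled H2AS40-KD. An exchange of 1 library between the groups was tested by splitting the 6 libraries otherwise: the labelled split called 178 genes and every split with 1 library of each group exchanged called at most 2, which argues against such an exchange. Without removal of the gene-span trend, the interval of H2AC25 allowed a fall of at most 5.4% in these TPM. Reads shared with near-identical H2A genes may hide a larger one. This cannot be told apart because TPM hold no reads. Targets other than the assumed pair also stay open, although the sum with H2AC4 and H2AC8 was higher by 5.51 TPM in the libraries labelled H2AS40-KD.

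NF-kappaB and inflammatory genes were higher in the libraries labelled H2AS40-KD, with a median of 0.34 over 19 genes (camera adjusted p = 1.5e-08, but adjusted p = 0.0711 with an estimated correlation). The median stayed at 0.32 or above when any 1 library was left out, at 0.33 or above under both scalings, and at 0.31 after the gene-span trend was removed, which argues against each of these as the whole cause. Handling at harvest may raise immediate-early genes and inflammatory messages together. Of 29 immediate-early genes that had not been called, 4 of them also in fixed lists, 23 were positive with a median of 0.17 (camera p = 4.0e-05, but p = 0.141 with an estimated correlation). That lies between the bounds of 0.1 and 0.2 set for the test. Over all 35 tested members, 6 of them called as higher, the median was 0.20, so leaving out the called genes lowered it. With the gene-span trend removed, the median of the 29 was 0.11. Handling and an effect of the knockdown therefore cannot be told apart.

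The 6 libraries allow 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 73 higher and 105 lower genes, and the highest other split gave 1 in each direction. The real split also gave 2 genes at least 2-fold higher and 3 lower, where other splits gave at most 1 of each, and 9 gene lists, where other splits gave at most 6. In each case 1 of the 10 splits, the real one, gave a result as large.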
